A study of Capra hircus with 40 samples.

How the data were processed

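Bulk RNA sequencing of whole ovary and whole uterus from female Jining gray goats was analysed at 4 ages: day 1 and months 2, 4 and 6 after birth. Each tissue and age held 5 libraries, 40 in 8 groups, with the group and individual number of each read from its label. Per the labels, total RNA was extracted with TRIzol and made into standard Illumina libraries. The labels speak of individuals, so the libraries of a group were taken as separate animals.

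The starting point was the authors' deposited table of whole-number counts per gene for the 40 libraries, with no normalization. Per the submitters' processing notes, fastp 0.23.1, HISAT2, StringTie 1.3.3b and RSEM 1.3.0 were used, with neither the role nor the order of each stated. The genome build, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense partners are uncertain to that extent. The table listed 30049 genes, of which 28910 carried an NCBI gene number and 1139 were loci assembled from the reads. All 28910 numbers were matched to symbols in a table of RefSeq genes for the goat assembly ARS1.2, used for names only, and 10710 of those symbols are LOC identifiers. CYP17A1 and CYP11A1 stand in that table as LOC102182663 and LOC102173131. No coordinates are given because the authors' build is not known. Assembled loci took between 1.16% and 5.47% of the counts of a library.

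Library totals ran from 31.9 to 62.7 M counts, with a median of 51.3 M, and between 19526 and 21948 genes were detected per library. At this depth a gene at 1 CPM, which scales counts to the library total, rests on many counts in each library, so the spread between animals sets the precision of most values. Intervals and floors given for genes at or near 0 cover counting error only. No pair of libraries of the same group agreed within sampling noise: the smallest chi-square per degree of freedom of any pair was 83.5, over genes with at least 10 counts, so every library was counted as 1 sample.

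Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, robust fit, TMM scaling, filterByExpr). Each tissue's 20 libraries were fitted together for the contrasts of month 2 with day 1, month 4 with month 2, month 6 with month 4 and month 6 with day 1. All 40 libraries were fitted together for the ovary against the uterus at day 1 and at month 6, and for the difference between tissues in the change from day 1 to month 6. The filter kept 19671 genes for the ovary, 18789 for the uterus and 20518 for both tissues. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, and all p-values are two-sided. Adjusted p-values of genes come from this edgeR fit unless another tool is named. Levels are given as CPM with the SD over the 5 libraries of a group, and fold changes as log2 with their standard error (SE). Where every library of a group was at 0, the fold is given as a lower bound against 3 counts over the group. Where a group held 1 to 3 counts in all, the ratio is given with its 95% counting interval.

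The 33 gene lists, the contrasts, the tests and the rule for named genes were fixed before the data were examined. The lists covered germ cells (oocyte, meiosis), follicle and steroid cells (granulosa, steroidogenesis and theca, cholesterol biosynthesis, ovulation and luteal), growth (cell cycle, fetal growth and imprinted, growth hormone with insulin and IGF, TGF-beta with anti-Mullerian hormone and BMP), tissue frame (extracellular matrix, smooth muscle, endothelial, mesothelial and ovarian surface, nerve and Schwann cell), the uterus (epithelial and gland, stroma and Mullerian patterning, steroid hormone receptors and their targets, oxytocin and prostaglandin, ciliated and oviduct epithelium), immunity (T and B lymphocyte, macrophage and other myeloid, antigen presentation, interferon response, complement), neighbouring or carried-over tissue (erythroid, skeletal muscle, adipocyte, adrenal) and cell state (immediate early and heat shock, hypoxia and glycolysis, oxidative phosphorylation, ribosomal protein). Lists were tested with camera in limma 3.58.1, against the other genes tested, with a preset correlation of 0.01 between the genes of a list. The input was the counts with their edgeR dispersions, which camera turns into normal scores. List scores and principal components used log CPM with a prior count of 2. The p-values were adjusted over the lists of a tissue's 4 contrasts, or of the 3 contrasts that hold both tissues. Every list was tested again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. Members of a list are counted as called over all genes tested and also with p adjusted over the list alone. Under 80% of the genes first written down were measured for the erythroid (57.1%), adrenal (36.4%), oxidative phosphorylation (56.7%) and skeletal muscle (79.2%) lists.

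The genes named in the text follow 3 parts of the rule. The first part is a set of reference genes for month 6 against day 1: 17 for the ovary and 14 for the uterus. The second takes, among called genes with a symbol other than a LOC identifier, no overlap between the libraries of the groups and at least 10 CPM in the higher group, the 6 with the largest rise and the 6 with the largest fall (4 and 4 between neighbouring ages). For the tissue difference the same part was applied without the request for no overlap. The third takes, for each called list, up to 4 called members with the smallest adjusted p. Members of a list named without a call, and genes named outside the rule, were chosen after their values were seen. Some genes that the rule takes are not reported here, though counts include them.

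Alternatives set in advance were DESeq2 1.42.0 (Wald test), limma-voom with sample quality weights, DESeq2 size factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 5 libraries, no limit on the fold, a fit of only the groups compared, the individual number as a block, and leaving out each library in turn. After the data were seen, 5 more were added: leaving out the pair of libraries that lack the markers of their tissue, that pair and a luteal ovary library, or the 3 uterus libraries with HOXA13 above 100 CPM, and fits with the ciliated gene score or the HOXA13 level of each library as a covariate. Python 3.11.15 with scipy 1.17.1 gave the permutation tests of the correlations.

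Whether the individual numbers pair libraries was checked before the fits with and without the block were compared. Deviations from the group means correlated between the same-numbered ovary and uterus libraries of an age with a median r of 0.071 across genes, and 9 of the 20 pairs exceeded 0.1. Clearer were genes on or off in single animals: 9 genes were on (at least 5 CPM) or off (at most 0.3 CPM) regardless of tissue, and same-numbered libraries of one age matched in 130 of 180 comparisons, above the highest of 100000 permutations of the numbers within age. Same-numbered ovary and uterus libraries of an age were therefore treated as from the same goat, and a tissue result is given with the block where the block changes it. Across ages the numbers do not pair animals (median r of -0.0548 between ovary libraries and 0.0285 between uterus libraries).

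Counts simulated for 3 comparisons had 200 genes changed by 1, 2 or 4 on the log2 scale. By size, edgeR recovered 26.9%, 89.6% and 97% for month 6 against day 1 in the ovary with 1 false call. It recovered 40.3%, 82.1% and 100% in the uterus with 5 false calls, and 26.9%, 88.1% and 97% for ovary against uterus at day 1 with 1 false call. Limma-voom made 3, 5 and 2 false calls and DESeq2 42, 36 and 26. The shifted list was called each time and 0 of 33 random lists were, with lists of correlated genes untested.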

Results

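Whole ovary and uterus of Jining gray goats were profiled by bulk RNA sequencing at day 1 and months 2, 4 and 6. The design asks how expression in each organ moves from birth through sexual maturation. Each group held 5 libraries, named here by organ, age and individual number. From day 1 to month 6 the group medians of total counts were 53.9, 52.5, 51.3 and 49.6 M in the ovary and 56.3, 50.2, 49.7 and 53.3 M in the uterus.

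The first principal component held 36.5% of the variance and parted the organs, with 1 exception. On it 19 ovary libraries lay between -166 and -30.2 and the 20 uterus libraries between 48.6 and 109, while ovary day 1 library 3 lay at 43.4. That library lacked the ovarian genes: FSHR, the follicle-stimulating hormone receptor of granulosa cells, was at 0.0809 CPM against at least 2.87 in each other ovary library, and ZP3, an egg coat glycoprotein, at 0. It held instead ADIPOQ, the fat cell hormone adiponectin, at 1830 CPM against at most 0.957. UCP1, the uncoupling protein of brown fat, was at 1510 against at most 0.327, and UPK3A, a bladder lining protein, at 175 against at most 3.46. Uterus month 4 library 5 was low in the uterine genes HOXA10 (3.19 CPM against at least 29.5 in each other uterus library) and EPCAM (9.41 against at least 89.4). The same library held ELN, which encodes elastin, at 11500 CPM against at most 134. Ovary month 4 library 5 was rich in genes of the corpus luteum. STAR, the cholesterol carrier of steroid synthesis, was at 2910 CPM against at most 56.9 in each other ovary library.

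**Figure D1:**
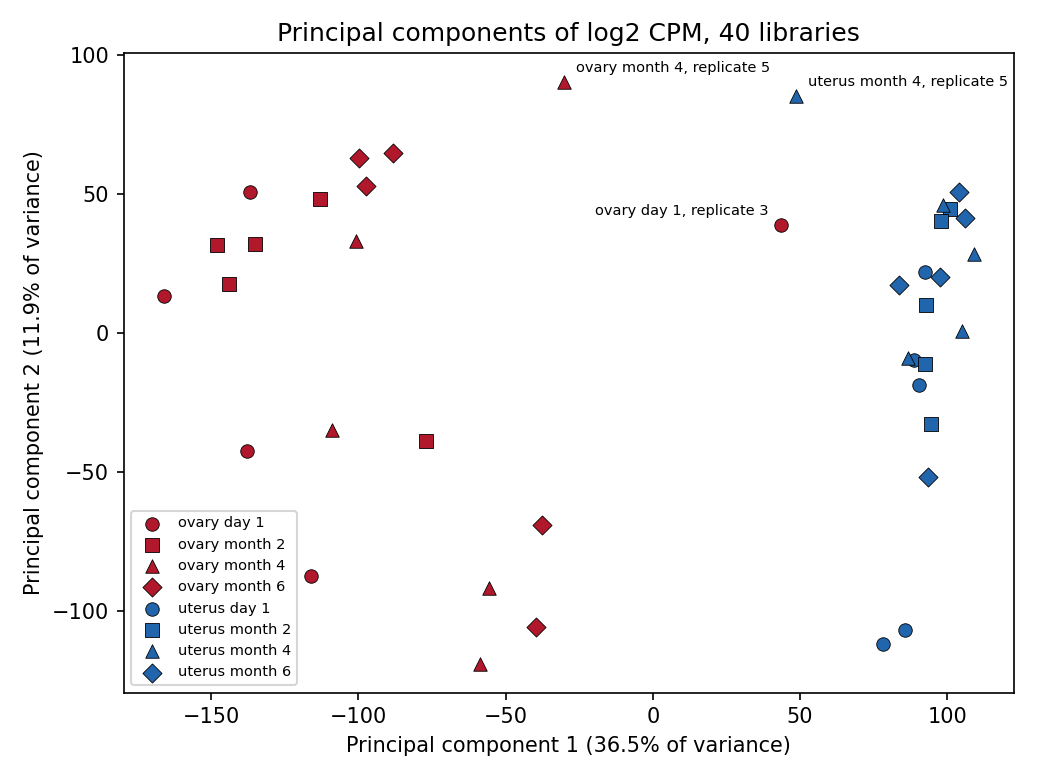
Scores of the 40 libraries on principal components 1 (36.5% of variance) and 2 (11.9%) of log2 CPM, with 1 point per library, colour for organ and shape for age. The organs separate along component 1 except for ovary day 1 library 3, 1 of 3 labelled libraries.

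From day 1 to month 6 the ovary lost oocyte, meiosis and cell cycle transcripts and gained those of lymphocytes and of immediate early response. The oocyte list (egg coat and egg-specific genes) fell by a median of 2.70 on the log2 scale, with 22 of 22 members lower (camera, adjusted p = 2.72e-09). The meiosis list fell by a median of 1.88, with 18 of 22 lower (adjusted p = 6.51e-06). Each had an adjusted p = 0.694 with an estimated correlation. None of their members was called over all genes. ZP2, an egg coat glycoprotein, was at 8.56 CPM at month 6 against 81.9 at day 1 (log2 fold change -3.21 ± 0.81 SE, n = 5). Adjusted over the list alone, 20 oocyte and 9 meiosis genes passed, all lower. The cell cycle list was lower in 35 of 35 members, with a median of -0.794 (adjusted p = 1.78e-15; adjusted p = 0.653 with an estimated correlation). Of them 3 passed when adjusted over the list alone. The fetal growth and imprinted list fell by a median of 0.65 (adjusted p = 3.92e-05; adjusted p = 0.226 with an estimated correlation). Adjusted over the list alone 6 members were lower. Without month 6 library 3 the cell cycle median was -1.29, and without day 1 library 3 the fetal growth one was -0.424.

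The T and B lymphocyte list was higher in 25 of 26 members, by a median of 1.14 (adjusted p = 1.78e-15). The immediate early and heat shock list was higher in 24 of 26, by a median of 0.943 (adjusted p = 1.13e-13). Each had an adjusted p = 0.226 with an estimated correlation. Over the list alone 13 lymphocyte genes passed, all higher, such as JCHAIN, the joining chain of antibody polymers (31.3 CPM against 9.7, 1.74 ± 0.39). So did 10 immediate early genes, all higher, such as FOS, a growth factor responsive regulator (56.4 CPM against 11.7, 2.29 ± 0.46). The calls of these 6 lists stood whichever library was left out. The lymphocyte median was 0.736 without month 6 library 2.

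**Figure D2:**
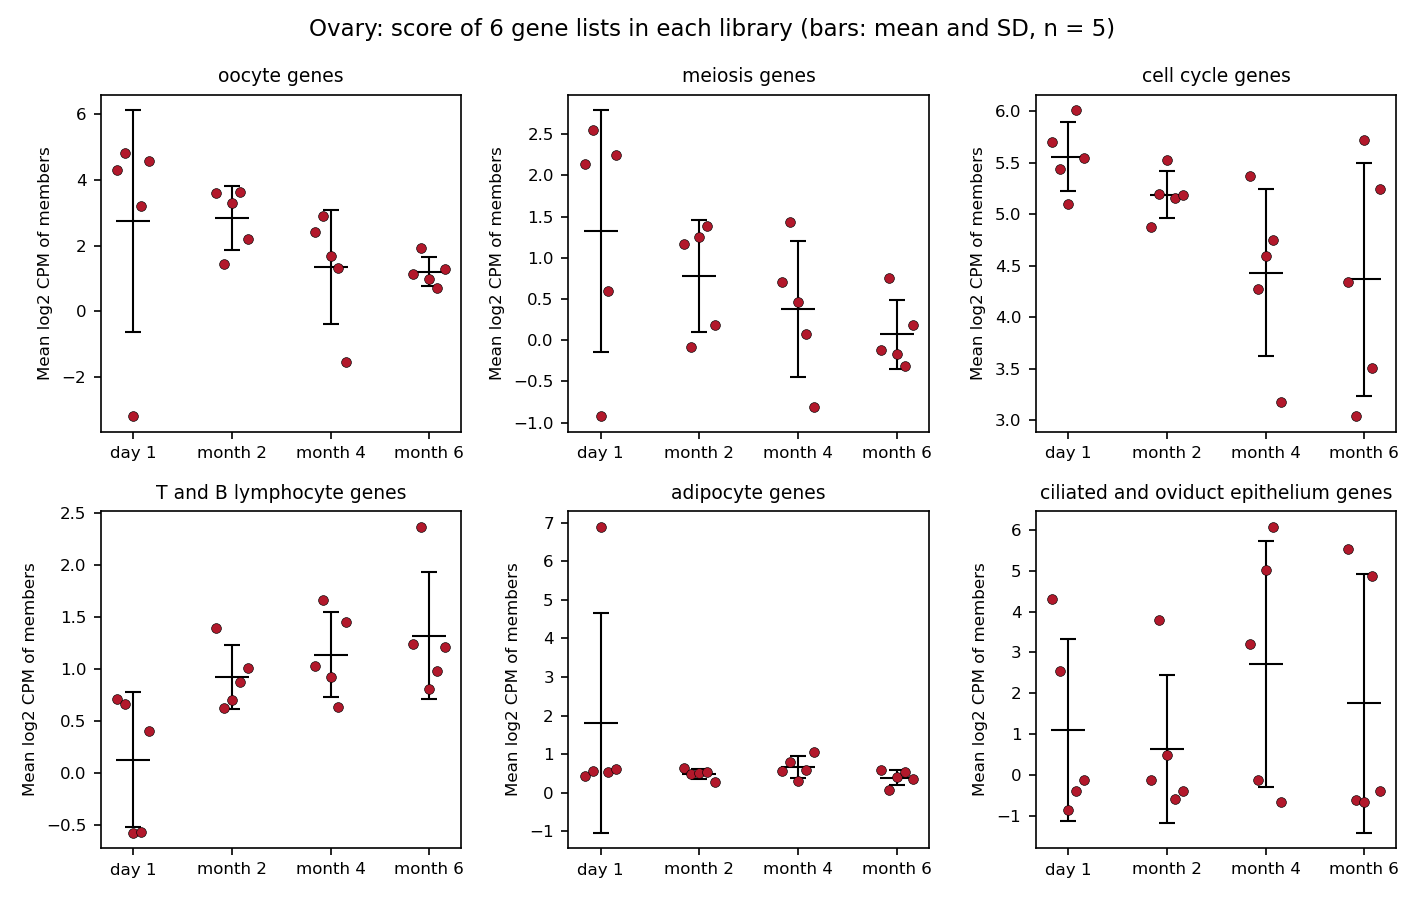
Scores of 6 gene lists (mean log2 CPM of the members) by age, with 1 point per library and mean ± SD bars (n = 5). The lymphocyte score is higher at month 6 than at day 1, and the adipocyte score stands apart in day 1 library 3.

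In edgeR 15 of 19671 differed between month 6 and day 1 in the ovary, 8 higher and 7 lower, while 2804 had an unadjusted p under 0.05. FBXO40, a muscle-associated ubiquitin ligase part, fell from 10.1 ± 3.82 CPM (SD) to 1.02 ± 0.321 (-3.26 ± 0.48, adjusted p = 0.00948). ADAMTS12, a matrix metalloprotease, fell from 54 ± 13.2 to 18 ± 4.04 (-1.55 ± 0.21, adjusted p = 0.0071). FHOD3, an actin organiser, fell from 13 ± 4.25 to 2.97 ± 0.651 CPM (-2.10 ± 0.32, adjusted p = 0.0108). VLDLR, a receptor for lipoproteins, fell from 58 ± 14.9 to 23.3 ± 4.59 (-1.28 ± 0.22, adjusted p = 0.0313). FHOD3 was not called without month 6 library 2 (adjusted p = 0.056). VLDLR was not called without day 1 libraries 1, 2 or 5 or month 6 libraries 2, 3, 4 or 5 (adjusted p from 0.0538 to 0.107). DESeq2 called 655 genes and limma-voom 1165, but a fit of only the groups compared called 0, with FBXO40 at an adjusted p = 0.0634 and the other 3 from 0.0907 to 0.235. The count of 15 became 322, holding all 15, without day 1 library 3. It became 93 without day 1 library 4, 7, 8 and 9 without day 1 libraries 1, 2 and 5, and 6 and 9 without month 6 libraries 2 and 4. In the fit without day 1 library 3 and uterus month 4 library 5, oocyte genes were called lower at month 6: GDF9, an oocyte growth factor (-2.81 ± 0.44, adjusted p = 0.0118), ZP3 (-3.72 ± 0.75, adjusted p = 0.0218) and DDX4, a germ cell helicase (-2.69 ± 0.60, adjusted p = 0.0316).

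With all libraries these 3 did not pass. GDF9 had 3.78 ± 0.944 CPM at month 6 and 22.4 ± 12.9 at day 1 (-2.52 ± 0.56, adjusted p = 0.0803). ZP3 had a log2 fold change of -3.40 ± 1.11 (adjusted p = 0.197) and DDX4 of -2.37 ± 0.81 (adjusted p = 0.206). None of the reference genes passed. FSHR was at 73.2 ± 68.9 CPM at month 6 and 80.3 ± 106 at day 1 (-0.15 ± 1.15). AMH, the anti-Mullerian hormone of small follicles, was at 80.2 ± 74.1 and 66.9 ± 96 (0.24 ± 1.24), and CYP19A1, the enzyme that forms estrogens, at 85.5 ± 170 and 10.9 ± 9.86 (2.96 ± 1.47). The steroid enzymes CYP11A1 (1.56 ± 1.44) and CYP17A1 (0.06 ± 1.27), STAR (-1.17 ± 1.43), the luteinizing hormone receptor LHCGR (0.42 ± 1.27), the inhibin subunit INHA (1.16 ± 1.10) and the granulosa regulator FOXL2 (0.55 ± 1.25) did not pass. Nor did SYCP3 of the meiotic chromosome axis (-2.55 ± 0.93), the proliferation marker MKI67 (-1.16 ± 0.77), the collagen COL1A1 (-1.19 ± 0.42) and the fetal growth factor IGF2 (-0.70 ± 0.40). The adjusted p of these 13 genes ran from 0.212 (COL1A1) to 0.99 (CYP17A1). Single libraries set some of these values. Without month 6 library 5 CYP19A1 was at -0.21 (adjusted p = 0.964), without month 6 library 2 DDX4 at -3.15 (adjusted p = 0.179) and without day 1 library 3 STAR at -0.28 (adjusted p = 0.954). Without day 1 library 4 CYP17A1 was at 2.71 (adjusted p = 0.27), INHA at 2.47, FOXL2 at 2.46, LHCGR at 1.98, AMH at 1.53, FSHR at 0.88 and MKI67 at -0.20 (adjusted p from 0.279 to 0.921).

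**Figure D3:**
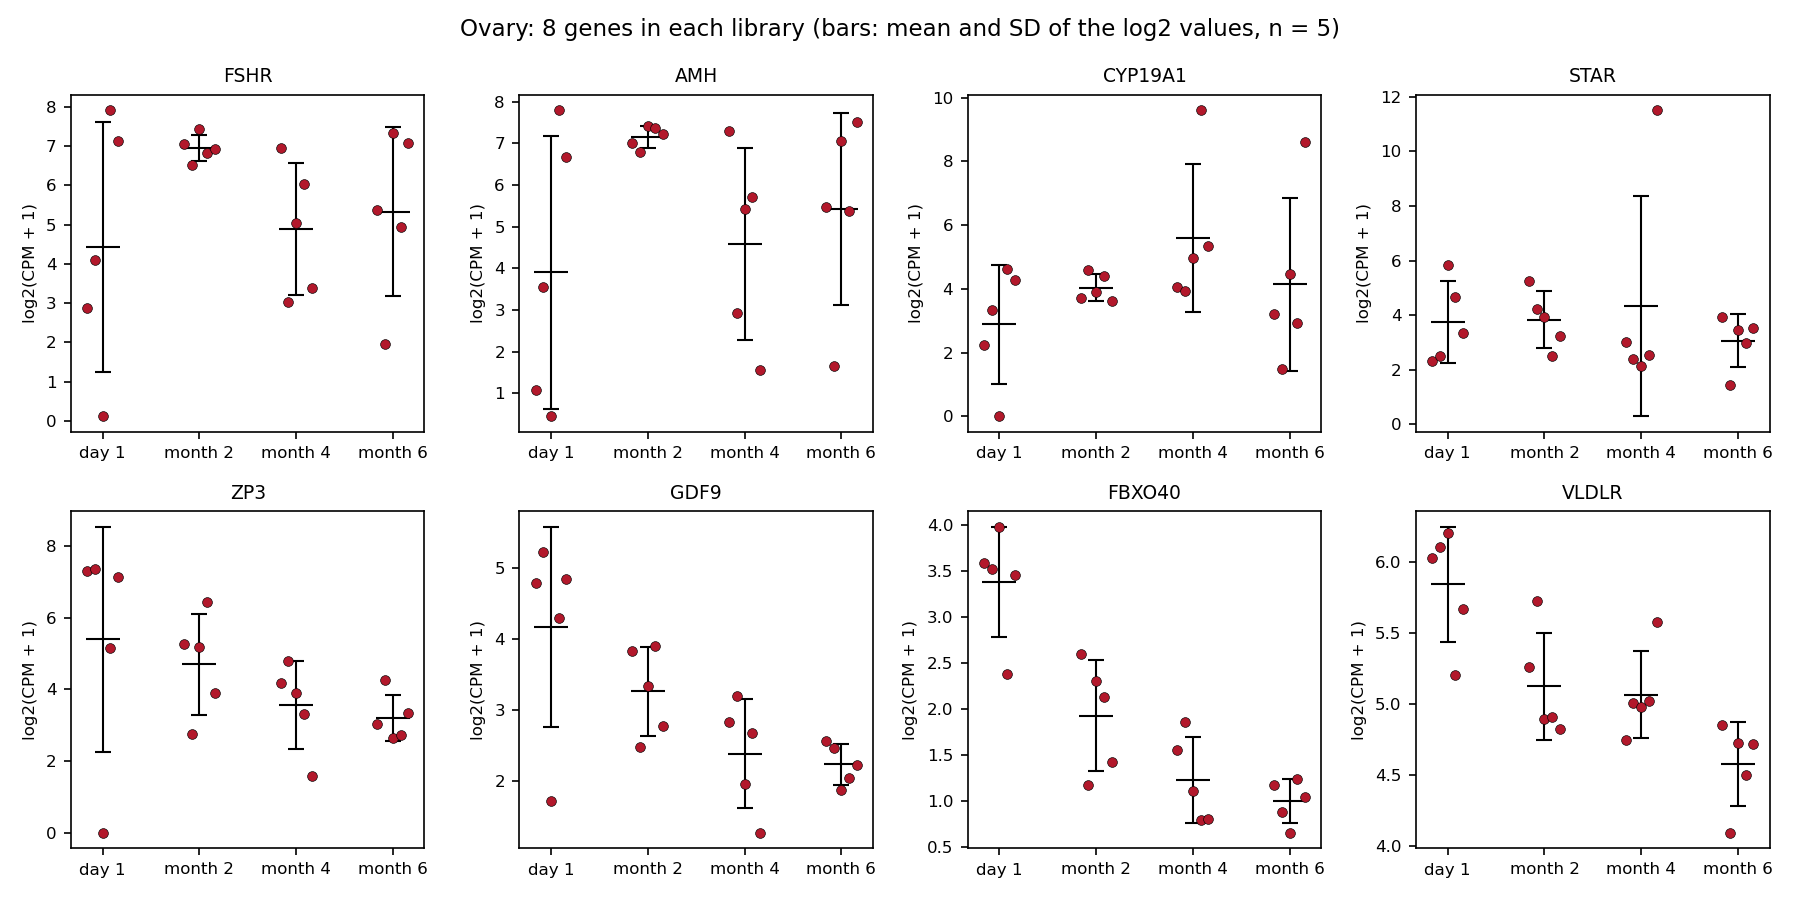
Levels of FSHR, AMH, CYP19A1, STAR, ZP3, GDF9, FBXO40 and VLDLR in the ovary as log2(CPM + 1) by age, with 1 point per library and mean ± SD bars (n = 5). FBXO40 and VLDLR are lower at month 6 than at day 1.

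Another 6 ovary lists passed between day 1 and month 6 only with particular libraries in the fit. The adipocyte list was lower in 14 of 14 members, with a median of -2.81 (adjusted p = 0.00101; adjusted p = 0.694 with an estimated correlation) and 12 members lower over the list alone. Its fat genes were highest in day 1 library 3, and without that library the median was -0.266 (adjusted p = 0.943). Extracellular matrix genes fell by a median of 0.552 (adjusted p = 0.0307; adjusted p = 0.819 with an estimated correlation). The call was lost without day 1 libraries 3 or 4 or month 6 libraries 1 or 4 (adjusted p from 0.0554 to 0.811). Erythroid genes, of red blood cells, fell by a median of 1.42 (adjusted p = 0.0356; adjusted p = 0.483 with an estimated correlation). This was lost without day 1 libraries 2, 3 or 5 or month 6 libraries 1 or 4 (adjusted p from 0.051 to 0.134). Ciliated and oviduct epithelium genes, whose score spanned at least 4.39 on the log2 scale within each age, were higher in 24 of 25 members by a median of 1.51 (adjusted p = 0.0343; adjusted p = 0.887 with an estimated correlation). This was lost without day 1 libraries 3, 4 or 5 or month 6 libraries 1 or 4 (adjusted p from 0.0884 to 0.805). Cholesterol biosynthesis genes were higher in 20 of 20 members by a median of 0.369 (adjusted p = 0.0282; adjusted p = 0.827 with an estimated correlation). This was lost without day 1 libraries 1 or 2 or month 6 libraries 1, 3 or 5 (adjusted p from 0.0645 to 0.331). Antigen presentation genes rose by a median of 0.198 (adjusted p = 0.0282; adjusted p = 0.713 with an estimated correlation). This was lost without day 1 libraries 1, 2 or 4 or month 6 library 1 (adjusted p from 0.0502 to 0.17). Without month 6 library 1, 8 lists were called in place of 13.

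The other 20 lists did not pass in the ovary. Their medians were -0.118 for granulosa cell genes (adjusted p = 0.139), 0.197 for steroidogenesis and theca (0.195), -0.00726 for ovulation and luteal (0.642), -0.0834 for steroid hormone receptors and targets (0.941), 0.0127 for oxytocin and prostaglandin (0.495), 0.338 for complement (0.0774), 0.0262 for growth hormone, insulin and IGF (0.632), -0.0902 for TGF-beta (0.895), -0.0955 for endothelial (0.941) and -0.0814 for hypoxia and glycolysis genes (0.927). The other 10 had an adjusted p from 0.195 to 0.909. The test pointed up for the granulosa, ovulation, receptor, endothelial, hypoxia and TGF-beta lists although their medians were negative, and down for the oxytocin list although its median was positive. The mean had the sign opposite to the median for granulosa (0.156), oxytocin (-0.237) and growth hormone genes (-0.0122).

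From day 1 to month 2 the lymphocyte list was called higher and the fetal growth list lower in the ovary. The T and B lymphocyte list was higher in 24 of 26 members, by a median of 0.671 (adjusted p = 8.61e-11; adjusted p = 0.419 with an estimated correlation). The fetal growth and imprinted list fell by a median of 0.608 (adjusted p = 4.95e-05), and erythroid genes by a median of 2.03 (adjusted p = 0.00443). Each had an adjusted p = 0.226 with an estimated correlation. Over the list alone 4 fetal growth genes passed, all lower. So did 1 erythroid gene, the beta globin HBBC (-4.33 ± 1.38). These 3 calls stood whichever library was left out. In edgeR 1 gene was called, the uncharacterised LOC108634738 (1.63 ± 0.24, adjusted p = 0.0361), a gene named after its value was seen, and 1488 genes had an unadjusted p under 0.05. The count was 0 without day 1 library 3 and uterus month 4 library 5, and DESeq2 called 45 genes.

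Another 11 lists called at that step each lost the call without at least 1 single library. Adipocyte genes (median -3.05, 11 lower over the list alone, adjusted p = 0.000185) and smooth muscle genes (-0.763, 5 lower over the list alone, adjusted p = 8.87e-05) had an adjusted p = 0.694 with an estimated correlation. Without day 1 library 3 they had medians of -0.147 and -0.133 (adjusted p = 0.874 and 0.597).

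From month 2 to month 4 the ovary lost oocyte and cell cycle transcripts and gained complement ones. Oocyte genes were lower in 21 of 22 members, by a median of -1.01 (adjusted p = 1.96e-07). Cell cycle genes had a median of -0.584 (adjusted p = 1.21e-09). Ciliated genes, which also differed widely within each age, were higher in 25 of 25 members, by a median of 2.78 (adjusted p = 5.94e-07). Each of these 3 lists had an adjusted p = 0.694 with an estimated correlation. Complement genes were higher in 14 of 15 members, by a median of 1.11 (adjusted p = 6.23e-08; adjusted p = 0.512 with an estimated correlation). These 4 calls stood whichever library was left out. The cell cycle and complement medians were -0.389 and 0.719 without month 4 library 5, the ciliated one 4.96 without month 2 library 2. In edgeR 0 genes were called, with 1751 at an unadjusted p under 0.05, while DESeq2 called 24 and limma-voom 5.

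Another 5 lists called from month 2 to month 4 each lost the call without at least 1 month 4 library. Cholesterol biosynthesis genes were higher in 20 of 20 members (median 1.40, adjusted p = 1.75e-06; adjusted p = 0.694 with an estimated correlation), 8 of them over the list alone. Interferon response genes were higher in 26 of 27 (median 1.33, adjusted p = 5.05e-06; adjusted p = 0.713 with an estimated correlation). Month 4 library 5, rich in luteal genes, held the interferon-induced ISG15 at 487 CPM against at most 25 in each other ovary library. Without it the medians were 0.0788 for cholesterol (adjusted p = 0.493) and -0.0447 for interferon genes (adjusted p = 0.786).

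From month 4 to month 6 immediate early genes rose in the ovary, by a median of 0.488 (adjusted p = 4.12e-09; adjusted p = 0.226 with an estimated correlation). Interferon response genes were lower in 27 of 27 members (-1.03, adjusted p = 3.08e-07). Cholesterol biosynthesis genes had a median of -1.01 (adjusted p = 0.000407) and steroidogenesis and theca genes of -1.22 (adjusted p = 0.0307), with STAR at 8.68 CPM against 585 (-6.06 ± 1.75). With an estimated correlation these 3 lists had an adjusted p = 0.694, 0.748 and 0.713. Without month 4 library 5, rich in luteal genes, the medians were 0.143 (adjusted p = 0.0152), 0.335 (adjusted p = 0.00229) and 0.000275 (adjusted p = 0.676), so the first 2 were called higher. Cholesterol was not called without month 6 library 2 (adjusted p = 0.146), nor steroidogenesis without month 6 libraries 1, 2 or 4 (adjusted p from 0.0773 to 0.384). Another 6 called lists each lost the call without at least 1 single library. Without month 4 library 5, 17 lists were called in place of 11. In edgeR 0 genes were called, with 520 at an unadjusted p under 0.05, while DESeq2 called 4 and limma-voom 0.

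In the uterus, 266 of 18789 genes differed between month 6 and day 1, 124 higher and 142 lower. GRP, which encodes gastrin-releasing peptide, rose from 0.108 ± 0.148 to 1340 ± 2620 CPM (SD, n = 5; log2 fold change 13.60 ± 1.88 SE, adjusted p = 0.00349). FAM162B rose from 0.56 ± 0.434 to 13.4 ± 11 CPM (4.53 ± 0.81, adjusted p = 0.013). KERA, a small proteoglycan of the matrix, fell from 72.1 ± 33.7 to 6.47 ± 2.68 CPM (-3.50 ± 0.64, adjusted p = 0.0139). LUZP2 fell from 17.6 ± 8.52 to 0.582 ± 0.404 (-4.94 ± 0.94, adjusted p = 0.0174), and UCHL1, a ubiquitin hydrolase of neurons and germ cells, from 25.3 ± 4.91 to 5.84 ± 3.73 (-2.13 ± 0.34, adjusted p = 0.00807). These 5 calls stood whichever library was left out.

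A further 18 genes that the rule names were called in the uterus between day 1 and month 6, 14 of them given here, with adjusted p from 0.022 (CHST9) to 0.0494 (NEFM). Higher were SERPINA14, the secreted uterine serpin of gland cells (1260 ± 2780 CPM against 0.0636 ± 0.0818; 14.15 ± 2.94) and the chemokine gene CXCL14 (7.69 ± 1.82). Of the prostaglandin genes, PTGS2, the inducible cyclooxygenase (5.94 ± 1.36), and PTGER2, a prostaglandin E receptor (4.26 ± 0.90), rose, while PTGES, a prostaglandin E synthase, fell (-2.67 ± 0.66). LYVE1, of lymphatic endothelium, rose (1.44 ± 0.32). Lower were the fetal growth factor IGF2 (-1.53 ± 0.35), the fetal RNA-binding proteins IGF2BP3 (-1.84 ± 0.39) and IGF2BP2 (-1.16 ± 0.28), and the interferon-induced MX2 (-2.96 ± 0.68). Lower too were the epithelial FXYD3 (-8.73 ± 2.03), JAKMIP2 (-5.33 ± 1.24), the sulfotransferase CHST9 (-5.06 ± 1.02) and the neurofilament NEFM (-6.24 ± 1.56).

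Of the 23 named calls, 16, 11, 17, 6 and 13 were lost without day 1 libraries 1 to 5 in turn, and 12, 18, 9, 11 and 7 without month 6 libraries 1 to 5. Month 6 library 2 held the highest SERPINA14, GRP, CXCL14, PTGS2 and PTGER2 of its group. Without it GRP was at 10.58 (adjusted p = 0.00106), SERPINA14 at 7.86 (adjusted p = 0.0573), CXCL14 at 3.01 (adjusted p = 0.202), PTGS2 at 2.27 (adjusted p = 0.171) and PTGER2 at 2.58 (adjusted p = 0.084). Without day 1 library 3, MX2 was at -1.82 (adjusted p = 0.114), PTGES at -2.05 (adjusted p = 0.136) and NEFM at -4.82 (adjusted p = 0.132). The count of 266 became 107, 146 and 76 without day 1 libraries 1, 2 and 3, and 133, 107 and 145 without month 6 libraries 1, 2 and 4. HOXA13, a gene of the lower end of the genital tract, was at 26.6, 4.18, 120, 0.609 and 138 CPM in day 1 libraries 1 to 5 and at most 1.67 at month 6. Without the 3 uterus libraries above 100 CPM of HOXA13, 2 from day 1 and 1 from month 2, 109 genes were called, 68 of them among the 266, and FXYD3 was at -0.74. With the HOXA13 level as a covariate 2 genes were called, and none of the 23 named.

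**Figure D4:**
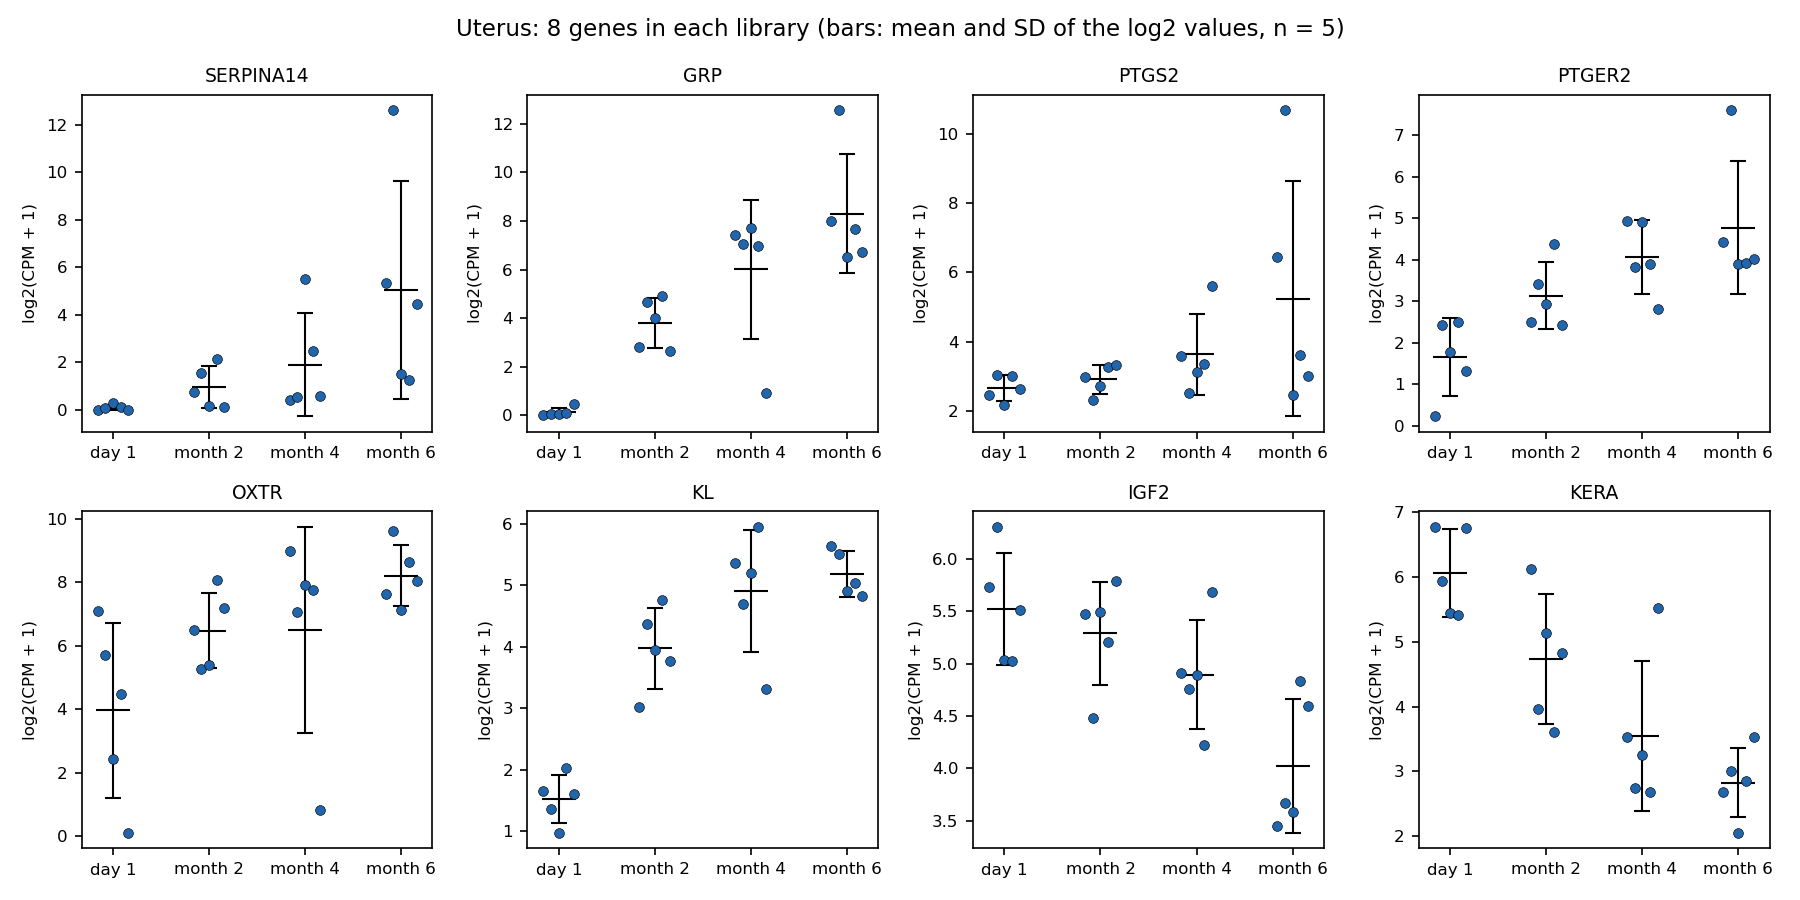
Levels of SERPINA14, GRP, PTGS2, PTGER2, OXTR, KL, IGF2 and KERA in the uterus as log2(CPM + 1) by age, with 1 point per library and mean ± SD bars (n = 5). GRP is higher and KERA and IGF2 lower at month 6 than at day 1.

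Reference genes of the uterus other than IGF2 did not pass. ESR1, the estrogen receptor, was at 925 ± 197 CPM at month 6 and 403 ± 185 at day 1 (1.18 ± 0.44). PGR, the progesterone receptor, was at 409 ± 109 and 150 ± 47.9 (1.43 ± 0.40), and OXTR, the oxytocin receptor, at 358 ± 261 and 42.9 ± 56.5 (3.05 ± 1.22). The implantation cytokine LIF (1.96 ± 0.56), the growth factor IGF1 (1.18 ± 0.51), the gland regulator FOXA2 (1.24 ± 0.87), HOXA10 (-0.26 ± 0.53), the Wnt ligand WNT7A (-1.44 ± 0.83), EPCAM (-0.15 ± 0.51), the smooth muscle genes ACTA2 (0.75 ± 0.62) and MYH11 (0.76 ± 0.38), MKI67 (-2.68 ± 1.16) and COL1A1 (-0.62 ± 0.85) did not pass either. The adjusted p of these 13 genes ran from 0.0798 (PGR) to 0.918 (EPCAM). Without day 1 library 1 OXTR was at 4.21 (adjusted p = 0.14), and without month 6 library 5 WNT7A at -2.13 (adjusted p = 0.224).

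Lymphocyte, smooth muscle and endothelial genes rose and cell cycle, interferon, fetal growth, ciliated and nerve genes fell between day 1 and month 6 in the uterus. These 8 calls stood whichever library was left out. Lymphocyte genes were higher in 23 of 27 members, by a median of 1.45 (adjusted p = 3.98e-08). Cell cycle genes were lower in 35 of 35, by a median of -1.92 (adjusted p = 1.3e-15). Each had an adjusted p = 0.56 with an estimated correlation. Over the list alone 10 lymphocyte genes were higher and 1 lower. Likewise 5 cell cycle genes were lower. Fetal growth genes had a median of -1.16 (adjusted p = 4.11e-05) with 8 lower and 1 higher over the list alone. Nerve and Schwann cell genes had a median of -1.03 (adjusted p = 0.00631) with 5 lower and 2 higher. Each had an adjusted p = 0.536 with an estimated correlation. Interferon response genes were lower in 26 of 27 members (-0.838, adjusted p = 3.37e-08), smooth muscle genes higher in 22 of 23 (0.527, adjusted p = 0.000409). Endothelial genes had a median of 0.375 (adjusted p = 0.00305), and ciliated genes were lower in 26 of 26 (-2.14, adjusted p = 0.000141). With an estimated correlation these 4 had an adjusted p = 0.619, 0.733, 0.758 and 0.77. Without day 1 library 3 the interferon median was -0.443, and the ciliated one was -1.38 without day 1 library 5 and -4.39 without month 6 library 3.

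The other 5 uterus lists called between day 1 and month 6 each lost the call without at least 1 single library. Oxytocin and prostaglandin genes had a median of 0.631 (adjusted p = 0.0151; adjusted p = 0.56 with an estimated correlation), with 2 higher and 1 lower over the list alone. They were not called without day 1 library 5 (adjusted p = 0.0612). Immediate early genes had a median of 0.676 (adjusted p = 0.000436; adjusted p = 0.622 with an estimated correlation) and were not called without month 6 library 2 (adjusted p = 0.0625). Myeloid genes (-0.38, adjusted p = 0.0286; adjusted p = 0.814 with an estimated correlation) were not called without day 1 libraries 1 or 2 or month 6 library 4 (adjusted p from 0.0929 to 0.443). Meiosis genes (-0.681, adjusted p = 0.0183; adjusted p = 0.612 with an estimated correlation) were not called without month 6 libraries 1 or 2 (adjusted p = 0.0694 and 0.114). The 7 oocyte genes measured in the uterus had a median of -1.49 (adjusted p = 0.035; adjusted p = 0.536 with an estimated correlation), in which the called member was UCHL1. They were not called without day 1 libraries 1 or 3 or month 6 libraries 1 or 2 (adjusted p from 0.0517 to 0.0788). Without the libraries above 100 CPM of HOXA13, the ciliated (1.44, adjusted p = 0.374), endothelial (0.248, adjusted p = 0.146), smooth muscle (0.258, adjusted p = 0.379), oxytocin (0.405, adjusted p = 0.225) and oocyte lists (-0.183, adjusted p = 0.126) were not called. Of the uncalled lists, the test pointed down for granulosa (median -0.159, mean 0.212) and TGF-beta genes (-0.234, mean 0.123) and up for steroidogenesis (-0.0734, mean 0.0354) and Mullerian patterning genes (-0.0744, mean -0.104).

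**Figure D5:**
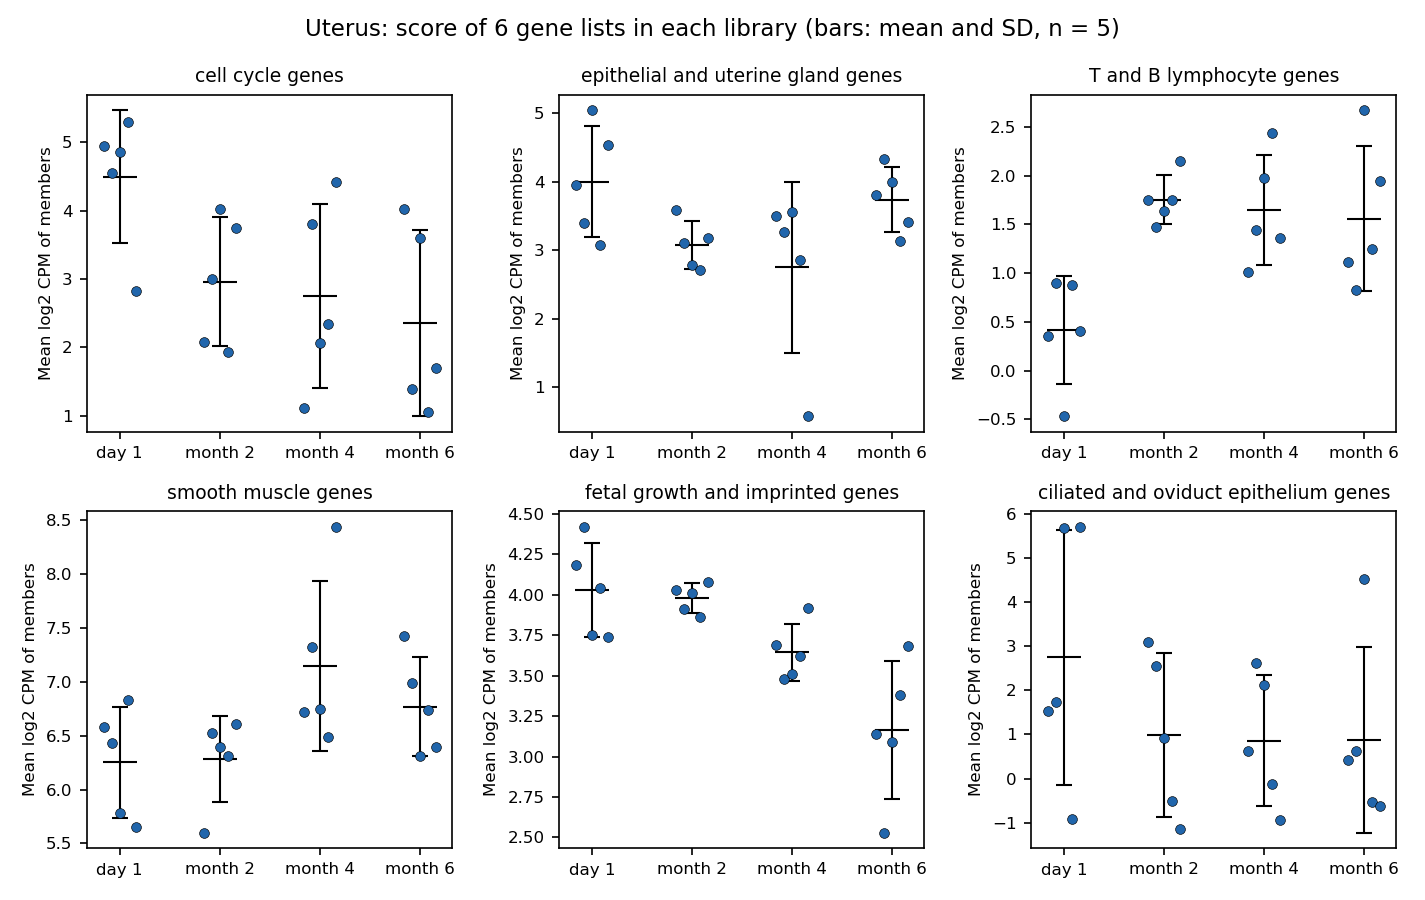
Scores of 6 gene lists (computed as for the ovary) by age, with 1 point per library and mean ± SD bars (n = 5). Cell cycle and fetal growth scores are lower and lymphocyte and smooth muscle scores higher at month 6 than at day 1.

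From day 1 to month 2 the lymphocyte list was called higher in the uterus and the epithelial, cell cycle, interferon and cholesterol lists lower. Lymphocyte genes were higher in 24 of 27 members, by a median of 1.44 (adjusted p = 1.3e-15; adjusted p = 0.536 with an estimated correlation), 14 of them over the list alone. Cell cycle genes had a median of -1.68 (adjusted p = 3.01e-12) and epithelial and gland genes of -0.974 (adjusted p = 1.31e-08). Interferon response genes had a median of -0.744 (adjusted p = 7.61e-09) and cholesterol genes of -0.672 (adjusted p = 1.34e-06). With an estimated correlation these 4 lists had an adjusted p = 0.616, 0.612, 0.619 and 0.619. Oxidative phosphorylation genes had a median of -0.336 (adjusted p = 0.000902), endothelial genes of 0.315 (adjusted p = 0.00582) and ciliated genes, lower in 26 of 26 members, of -2.74 (adjusted p = 4.47e-06). With an estimated correlation these had an adjusted p = 0.758, 0.77 and 0.733. Without the libraries above 100 CPM of HOXA13 they were not called (-0.176, 0.191 and 0.164, adjusted p = 0.193, 0.173 and 0.801), nor was Mullerian patterning (-0.015, adjusted p = 0.334). These 8 calls stood whichever single library was left out, and the interferon median was -0.46 without day 1 library 3. The last of the 9 called lists, Mullerian patterning (0.212, adjusted p = 0.0122; adjusted p = 0.622 with an estimated correlation), was lost without day 1 libraries 3 or 5 or month 2 library 5 (adjusted p from 0.0513 to 0.0961).

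In edgeR 3 genes rose at that step. KL, which encodes klotho, a co-receptor of fibroblast growth factors, was at 16 ± 7.21 CPM against 1.95 ± 0.772 (3.01 ± 0.44, adjusted p = 0.0147). KCNA3, a potassium channel of lymphocytes, was at 11.4 ± 3.38 against 2.6 ± 1.23 (2.10 ± 0.35, adjusted p = 0.0455). The last of the 3 was the uncharacterised LOC102175896, named after its value was seen. Without day 1 libraries 1, 2 or 3 or month 2 libraries 2 or 4, KL was not called (adjusted p from 0.0503 to 0.0794) and the count of 3 became 1. KCNA3 was not called without day 1 libraries 1, 2 or 3 or any 1 of the month 2 libraries (adjusted p from 0.0593 to 0.134). The count became 12 without day 1 library 4 and 5 without month 2 library 5. DESeq2 called 273 and limma-voom 274.

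From month 2 to month 4 smooth muscle and cholesterol genes rose in the uterus. Smooth muscle genes were higher in 22 of 23 members, by a median of 0.984 (adjusted p = 1.95e-17; adjusted p = 0.536 with an estimated correlation), 8 of them over the list alone. Cholesterol biosynthesis genes were higher in 20 of 20 members, by a median of 0.775 (adjusted p = 1.61e-12; adjusted p = 0.56 with an estimated correlation), 6 of them over the list alone. Immediate early genes had a median of 0.633 (adjusted p = 9.63e-07; adjusted p = 0.582 with an estimated correlation). These 3 calls stood whichever library was left out. Without month 4 library 5, low in uterine genes, the smooth muscle median was 0.558 and the immediate early one 0.256. The cholesterol one was 0.334 without month 4 library 2. In edgeR 0 genes were called, with 1244 at an unadjusted p under 0.05, while DESeq2 called 24 and limma-voom 0.

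Another 6 lists called from month 2 to month 4 each lost or turned the call without at least 1 single library. Extracellular matrix genes had a median of 0.989 (adjusted p = 0.00179; adjusted p = 0.788 with an estimated correlation), with ELN at 2340 CPM against 79.8 (4.89 ± 1.34). Interferon response genes had a median of 0.703 (adjusted p = 3.37e-08; adjusted p = 0.619 with an estimated correlation). Without month 4 library 5, low in uterine genes, which held ISG15 at 163 CPM against at most 46.1 in each other uterus library, the medians were -0.28 for matrix, called lower (adjusted p = 0.000289), and 0.201 for interferon genes (adjusted p = 0.14).

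From month 4 to month 6 epithelial and gland genes were higher in 25 of 28 members in the uterus, by a median of 0.863 (adjusted p = 4.58e-11). Fetal growth genes fell by a median of 0.415 (adjusted p = 0.00244). Each had an adjusted p = 0.56 with an estimated correlation. Over the list alone 3 epithelial genes were higher. Oxidative phosphorylation genes rose (0.292, adjusted p = 6.97e-05; adjusted p = 0.71 with an estimated correlation). These 3 calls stood whichever library was left out. The epithelial median was 0.617 without month 4 library 5, the fetal growth one -0.174 without month 6 library 2. The oxidative phosphorylation one was 0.147 and 0.485 without month 4 libraries 1 and 2 and 0.161 without month 6 library 1. Extracellular matrix (-0.874, adjusted p = 0.00568), smooth muscle (-0.59, adjusted p = 0.000409) and interferon response genes (-0.787, adjusted p = 7.43e-08) had an adjusted p = 0.814, 0.733 and 0.619 with an estimated correlation. Without month 4 library 5 they were at 0.186, -0.15 and -0.243 (adjusted p = 0.0156, 0.414 and 0.0646), so matrix genes were called higher. They were not called without month 6 libraries 4 or 5 (adjusted p = 0.0663 and 0.0525). Complement, also among the 8 called lists, lost its call without any 1 of 5 libraries. The 8 became 13 without month 4 library 1 or month 6 library 3. In edgeR 0 genes were called, with 2028 at an unadjusted p under 0.05, while DESeq2 called 56 and limma-voom 0.

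Between the organs at day 1, 2913 of 20518 genes differed, 2104 higher in the ovary and 809 higher in the uterus. All 22 oocyte genes were higher in the ovary and called, by a median of 7.25 (camera, adjusted p = 6.82e-20; adjusted p = 0.394 with an estimated correlation). GDF9 was at 22.4 ± 12.9 CPM in the ovary and 1.68 ± 0.297 in the uterus (3.73 ± 0.47) and ZP3 at 99.6 ± 76.6 and 0.0991 ± 0.159 (9.99 ± 1.42; adjusted p at most 1.16e-05 for each). ZP4, another egg coat gene, was 10900-fold higher (counting interval 3730 to 52900). Meiosis genes had a median of 2.01 (adjusted p = 4.4e-05), with 11 called higher and 13 over the list alone. Granulosa cell genes had a median of 2.75 (adjusted p = 6.41e-05), with 10 called higher and 14 over the list alone, and of 1.69 without ovary library 4. Steroidogenesis and theca genes had a median of 0.962 (adjusted p = 0.00419), with 5 called higher and 7 over the list alone. Each of these 3 lists had an adjusted p = 0.624 with an estimated correlation. Among the meiosis genes SPATA22 was 1520-fold higher (272 to 60100; 961-fold without ovary library 2) and SYCP3 710-fold (127 to 28100).

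Of the granulosa genes at day 1, FSHR was at 80.3 ± 106 and 0.0241 ± 0.0379 CPM (11.66 ± 1.66). AMH (10.19 ± 1.52) and INHA (6.25 ± 1.12) were higher too. Of the steroid genes, CYP17A1 was at least 3310-fold higher, with NR5A1 at 9.70 ± 1.29, CYP11A1 at 10.37 ± 1.93 and LHCGR at 7.89 ± 1.54 (adjusted p at most 0.000419 for each of these genes). Without ovary library 4 AMH was at 8.95, INHA at 4.99, LHCGR at 6.38 and CYP17A1 at least 588-fold higher. Cell cycle genes had a median of 0.84 (adjusted p = 0.000459; adjusted p = 0.919 with an estimated correlation; 0.602, adjusted p = 0.0509 without the uterus libraries above 100 CPM of HOXA13), with 4 called higher, such as the mitotic kinases AURKA (3.90 ± 0.85) and PLK1 (1.31 ± 0.32).

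Higher in the day 1 uterus were epithelial and gland genes, with a median of -2.32 for ovary against uterus (adjusted p = 7.9e-08; adjusted p = 0.624 with an estimated correlation), 7 called lower and 2 higher in the ovary, and 14 and 3 over the list alone. SOX17, a regulator of uterine glands, was at -3.15 ± 0.46 (adjusted p = 1.58e-05). Mullerian patterning genes had a median of -0.643 (adjusted p = 0.0298; adjusted p = 0.624 with an estimated correlation; adjusted p = 0.0539 with the animal as a block), with 7 called lower and 2 higher, and 9 and 3 over the list alone. They were not called without ovary library 3 or uterus libraries 2 or 4 (adjusted p from 0.059 to 0.0695). HAND2 (-5.92 ± 1.19) and MSX1 (-3.11 ± 0.55) of uterine stroma were higher in the uterus and TCF21, a mesenchymal regulator, in the ovary (2.75 ± 0.31).

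Antigen presentation genes were lower in the day 1 ovary than in the uterus, with a median of -0.486 (adjusted p = 0.00234; adjusted p = 0.624 with an estimated correlation), and CIITA (-1.92 ± 0.42) and CD74 (-1.44 ± 0.37) were among those called. Myeloid genes had a median of -0.394 (adjusted p = 0.0305) and interferon response genes of -0.535 (adjusted p = 0.00878), each with an adjusted p = 0.919 with an estimated correlation. The myeloid list was not called without ovary libraries 1, 2 or 4 or uterus libraries 1 or 2 (adjusted p from 0.0532 to 0.296). The interferon list was not called without ovary library 4 or uterus library 3 (adjusted p = 0.0874 and 0.187). Without ovary library 3 their medians were -0.969 and -0.88. Ciliated genes were lower in 26 of 26 members (-1.99, adjusted p = 0.00878; adjusted p = 0.919 with an estimated correlation; adjusted p = 0.0695 with the animal as a block). They were not called without ovary library 3 or uterus libraries 3 or 5 (adjusted p from 0.0957 to 0.157). Without the uterus libraries above 100 CPM of HOXA13 the ciliated median was 1.6 (adjusted p = 0.552) and the interferon one -0.325 (adjusted p = 0.232). Adipocyte genes had a median of 4.74 (adjusted p = 0.00173; adjusted p = 0.795 with an estimated correlation), with 13 called higher in the ovary and 14 over the list alone. Among them were PPARG (5.47 ± 0.66), ADIPOQ (10.87 ± 2.06) and DGAT2 (4.96 ± 0.95). Without ovary library 3, rich in fat genes, the median was 0.413 (adjusted p = 0.566), ADIPOQ was at 0.67 (adjusted p = 0.762) and DGAT2 at 0.77 (adjusted p = 0.259). With the animal as a block these genes were at 1.96 and 1.42 (adjusted p = 0.494 and 0.208).

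At month 6, 2075 genes differed between the organs, 1241 higher in the ovary and 834 higher in the uterus. Oocyte genes were again higher in the ovary, with 19 called and 22 over the list alone (median 5.79, and 5.62 with genes at 0 set at their bound; adjusted p = 1.1e-21; adjusted p = 0.347 with an estimated correlation). ZP3 was at 9.09 ± 5.34 CPM in the ovary and 0.0566 ± 0.0658 in the uterus (7.27 ± 1.32, adjusted p = 0.000337). ZP4 was 1590-fold higher (439 to 13100). Granulosa cell genes had a median of 2.49 (adjusted p = 7.72e-08; adjusted p = 0.436 with an estimated correlation), 11 called higher and 1 lower, and 12 and 1 over the list alone. AMH was at 11.26 ± 1.61 (adjusted p = 2.32e-05), FSHR at 10.41 ± 1.54 (adjusted p = 4.63e-05), INHA at 8.20 ± 1.22 (adjusted p = 3.55e-05) and CYP19A1 at 11.76 ± 1.88 (adjusted p = 8e-05). Steroidogenesis and theca genes had a median of 0.86 (adjusted p = 0.000129; adjusted p = 0.454 with an estimated correlation), with 5 called higher and 6 over the list alone. CYP17A1 was at least 3570-fold higher and CYP11A1 at 11.26 ± 1.92. INSL3, a theca cell hormone, was at least 928-fold higher.

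Meiosis genes at month 6 had a median of 1.45, or 1.4 with bounds (adjusted p = 0.000883; adjusted p = 0.676 with an estimated correlation), with 7 called. Among them were MEI1 (3.74 ± 0.79) and SPATA22 (114-fold, 31.1 to 946; 61.8-fold without ovary library 2). Cell cycle genes had a median of 1.76 (adjusted p = 7.14e-12; adjusted p = 0.624 with an estimated correlation), with 8 called higher in the ovary and 21 over the list alone, such as AURKA (3.53 ± 0.84, adjusted p = 0.0046).

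Higher in the month 6 uterus were smooth muscle genes (-0.909, adjusted p = 9.05e-07; adjusted p = 0.624 with an estimated correlation), with 7 called and 10 over the list alone. Among them were DES, the muscle filament desmin (-2.84 ± 0.59, adjusted p = 0.00135), and the potassium channel KCNMA1 (-2.68 ± 0.40). Mullerian patterning genes had a median of -1.46 (adjusted p = 0.000459; adjusted p = 0.436 with an estimated correlation), with 8 called lower and 3 higher in the ovary, and 14 and 3 over the list alone. HOXD11 was at -8.59 ± 1.59 (adjusted p = 0.00039) and MSX1 at -3.41 ± 0.56, while TCF21 was higher in the ovary (2.48 ± 0.31). Epithelial and gland genes had a median of -1.22 (adjusted p = 7.92e-06; adjusted p = 0.757 with an estimated correlation), with 4 called lower and 1 higher (-1.93 without ovary library 1). SOX17 (-1.96 ± 0.44), CLDN4 (-4.16 ± 1.10) and SERPINA14 (-7.85 ± 1.83) were among the lower. Without uterus library 2, CLDN4 was at -2.73 (adjusted p = 0.0884) and SERPINA14 at -1.55 (adjusted p = 0.543). With the animal as a block SERPINA14 was at -2.09 (adjusted p = 0.468). Among the largest falls were those of GRP (-13.42 ± 1.61, adjusted p = 1.57e-06; -10.41 without uterus library 2), the calcium-binding S100G (-10.76 ± 1.67) and the ion channel MCOLN3 (uterus 4910-fold higher, 1360 to 40600; 2690-fold without uterus library 2).

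The change from day 1 to month 6 differed between the organs in 48 genes, 4 with a higher and 44 with a lower change in the ovary than in the uterus. JAKMIP2 fell in the uterus, and its change was 5.43 ± 1.24 higher on the log2 scale in the ovary (adjusted p = 0.05). CXCL14 rose in the uterus and differed by -8.51 ± 1.84 (adjusted p = 0.0368). The fat genes UCP1 (-12.46 ± 2.75, adjusted p = 0.0419), PCK1 (-14.23 ± 3.23, adjusted p = 0.05) and DGAT2 (-5.49 ± 1.22, adjusted p = 0.0437), with SNX31 (-10.86 ± 2.22, adjusted p = 0.0343) and C1QL3 (-6.39 ± 1.38, adjusted p = 0.0368), differed in the same direction as CXCL14. PCK1 was at 0 in the ovary at month 6, so that its fitted value is no bound. Without ovary day 1 library 3, in which fat genes were highest, UCP1 was at -1.11 (adjusted p = 0.915), PCK1 at -0.07 (adjusted p = 1), DGAT2 at -1.30 (adjusted p = 0.42), SNX31 at -5.24 (adjusted p = 0.133) and C1QL3 at -2.70 (adjusted p = 0.187). Without uterus month 6 library 2, CXCL14 was at -3.84 (adjusted p = 0.279). All 7 calls were lost without ovary month 6 libraries 1, 3, 4 or 5 or uterus day 1 libraries 1, 2, 3 or 5, and 6 or fewer without 11 others, with adjusted p from 0.0501. With the animal as a block 1 gene was called and none of the 7. The count of 48 became 23, 175 and 132 without ovary day 1 libraries 2, 3 and 4, and 6, 9, 8 and 6 without ovary month 6 libraries 1, 3, 4 and 5. It became 14, 9, 10 and 14 without uterus day 1 libraries 1, 2, 3 and 5, and 22 and 15 without uterus month 6 libraries 1 and 2.

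Among the lists, ciliated genes moved apart between the organs in 26 of 26 members, by a median of 3.67 toward the ovary (adjusted p = 7.9e-08; adjusted p = 0.771 with an estimated correlation). Interferon response genes did so by 0.716 (adjusted p = 0.000459; adjusted p = 0.919 with an estimated correlation). Without the uterus libraries above 100 CPM of HOXA13 these were 0.197 (adjusted p = 0.341) and 0.292 (adjusted p = 0.0594). The ciliated one was 6.16 without uterus month 6 library 3, and the interferon one 1.2, 0.454 and 0.341 without ovary day 1 library 3, ovary month 6 library 1 and uterus day 1 library 3. Adipocyte genes had a median of -3.68 (adjusted p = 2.23e-06), smooth muscle genes of -0.93 (adjusted p = 0.00215) and oxytocin and prostaglandin genes of -0.899 (adjusted p = 0.00604), with 6 of the last over the list alone, among them PTGS2 (-5.57 ± 1.32). With an estimated correlation these had an adjusted p = 0.624, 0.919 and 0.436. Without ovary day 1 library 3 they were not called (adjusted p = 0.566, 0.555 and 0.0645). Cell cycle genes (0.865, adjusted p = 0.000506), antigen presentation genes (0.362, adjusted p = 0.0111) and endothelial genes (-0.536, adjusted p = 0.0287) had an adjusted p = 0.919, 0.757 and 0.919 with an estimated correlation. They lost their calls without ovary month 6 library 3 (adjusted p = 0.149), without ovary month 6 library 1 (adjusted p = 0.097), and without any 1 of 7 libraries. Ribosomal protein genes were called in 6 of the comparisons within an organ: in the ovary from each age to the next (medians 0.419, -0.397 and 0.189) and from day 1 to month 6 (0.188), and in the uterus from month 2 to month 4 (-0.324) and to month 6 (0.28), with an adjusted p of at most 0.000131, and from 0.622 to 0.803 with an estimated correlation. These 6 calls stood whichever library was left out, though single libraries moved the last 4 medians to values as near 0 as 0.113, 0.113, -0.215 and 0.153. In none of the 11 comparisons did a list keep its call with an estimated correlation.

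Of the 18253 genes tested in both organs for month 6 against day 1, 8 rose and 7 fell in the ovary and 114 rose and 133 fell in the uterus. The shared calls were 1 riser, the uncharacterised LOC102185461, and 1 faller, CNTN3, a neuronal cell adhesion protein, both named after their values were seen. Independent lists would share 0.05 risers and 0.051 fallers, which leaves out the pairing by goat. With the individual number as a block, or with only the groups compared, 0 were shared. The 2 became 11, 7 and 3 without ovary day 1 libraries 3 and 4 and uterus month 6 library 5, and 1 without any 1 of 14 others.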

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

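The tests on libraries lacking their tissue's markers were chosen after the result was seen. The search for single libraries and tissue difference tests were planned. A library stood apart when its gap to the nearest other in its group exceeded 0.71 of the group's range. Normal values give this in about 5% of groups. Of 48 combinations of a library measure with a group 3 met this: the share of assembled loci in uterus month 2 library 1 (gap of 0.821 of the range), and the shares of TESK1 (0.848) and FBXO9 (0.801) in uterus day 1 library 5. Whether these counts (4.5% and 2.92% of the library) stem from the genes themselves was not tested. Of 301 such combinations for named genes 57 met it in CPM, which is too skewed for the 5% to hold.

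In ovary day 1, library 3 stood apart with ADIPOQ, PCK1, UCP1 and S100G (gap of 1 each, rounded), DGAT2 (0.994), SNX31 (0.992), C1QL3 (0.974) and LIPE (0.919), library 4 with CYP17A1 (0.872), MKI67 (0.831) and FOXL2 (0.744), and library 1 with IL1RL2 (0.844) and EMX2 (0.748). In ovary month 6, library 1 was high in GRP (0.809) and low in ADAMTS12 (0.718), library 2 high in the germ cell genes DDX4 (0.779), SYCP3 (0.765) and SPATA22 (0.737), library 3 low in C1QL3 (0.759), library 4 high in S100G (0.881) and DES (0.719), and library 5 high in CYP19A1 (0.951). In uterus day 1, library 2 was high in ADIPOQ (0.764), library 3 in MX2 (0.894), NEFM (0.851) and CDHR1 (0.735), library 4 in NR5A1 (0.715) and library 5 in GRP (0.816). In uterus month 2, library 5 was high in KCNA3 (0.746). In uterus month 6, library 2 was high in SERPINA14 (0.994), CXCL14 (0.977), GRP (0.972), PTGER2 (0.963), PTGS2 (0.949), CLDN4 (0.908), DGAT2 (0.834) and EPCAM (0.712). Library 1 of that group was high in C1QL3 (0.958), NR5A1 (0.836) and PRSS16 (0.821), library 3 in SNX31 (0.83), library 4 in INHA (0.843), and library 5 was low in CHST9 (0.71, rounded). A gap of 1 that rests on 1 to 10 counts, all in 1 library, and so says little, was met by LIPM and MCOLN3 in ovary day 1, MCOLN3 and PRSS16 in ovary month 6, SPATA22, SYCP3 and ZP4 in uterus day 1, and these 3, NEFM, CYP19A1 and CYP11A1 in uterus month 6. The change from day 1 to month 6 differed between the organs, in the test of the difference itself, for JAKMIP2 (5.43), PCK1 (-14.23), UCP1 (-12.46), SNX31 (-10.86), CXCL14 (-8.51), C1QL3 (-6.39) and DGAT2 (-5.49, all ovary minus uterus on the log2 scale).

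For the lack of tissue markers in ovary day 1 library 3 and uterus month 4 library 5, a swap between an ovary and a uterus library is argued against by FSHR, which reached at most 0.141 CPM in any uterus library, and low depth by the totals, the lower of which was 50.9 M counts. A library from another goat is argued against by 4 on-or-off genes chosen on the other 18 pairs, at which both matched their same-numbered partner in all 8 comparisons and no other number of their age matched at more than 3. Fat in the ovary day 1 library may be part of it: all 16 tested adipocyte list members were highest there, led by LPL (3770 CPM) and ADIPOQ (1830 CPM), while 10 of the 17 listed also reached 1 CPM in the median of the other 19 ovary libraries and 0 are in another list. Fat alone does not cover UPK3A (175 CPM) there. What uterus month 4 library 5 held stays open, and no biological explanation was tested because no group of the design sets these libraries apart.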

How the results depend on the processing

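The fits with the ciliated score or HOXA13 as a covariate and those without sets of libraries were chosen after the data were seen, and the other alternatives were planned. Among named genes that were called, 0 changed direction in any alternative, and calls were lost in 46 of 113 gene results with a fit of only the groups compared, 29 of 123 without the 3 uterus libraries rich in HOXA13, 23 of 25 with the HOXA13 covariate, 15 of 29 with the ciliated covariate, 24 of 127 with limma-voom, 17 of 127 without a filter and 7 of 127 without either set of libraries that lack markers. DESeq2, its size factors, the stricter filter and no fold limit lost 0. Depth limits only genes at or near 0. Where no reason is given, the cause was not tested.

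DESeq2 called 45 genes for ovary month 2 with day 1, 24 for month 4 with month 2, 4 for month 6 with month 4 and 655 for month 6 with day 1, 273, 24, 56 and 939 for the same uterus steps, 318 for the tissue difference and 89 the same way in both tissues (11 opposite ways, 13 expected from independent lists). Limma-voom with quality weights called 429, 5 and 1165 for ovary month 2 with day 1, month 4 with month 2 and month 6 with day 1, 274 and 524 for uterus month 2 and month 6 with day 1, 384 for the difference and 75 the same way in both (11 opposite, 15 expected). No filter gave 23 for the difference and 1 in both, and the stricter filter 11 for uterus month 2 with day 1 and 1 in both. A fit of only the groups compared, which rests on fewer libraries, gave 0 for ovary month 2 and month 6 with day 1, 0 and 81 for the uterus, 1203 and 1214 for the tissues at day 1 and month 6, 7 for the difference and 0 in both. Without the 2 libraries that lack their markers, and without these and the luteal one, month 6 with day 1 gave 322 and 855 genes in the ovary, with all 15 among them, and 496 both times in the uterus, with all 266. Month 2 with day 1 then gave 0 in the ovary and 39 in the uterus, the difference 207 and 307, both tissues 19 and 40 the same way (2 and 7 opposite, 3.2 and 7.4 expected), and 17 lists were called for ovary month 6 with month 4 without the 3 libraries. Without the 3 uterus libraries rich in HOXA13, 109 uterus genes and 19 for the difference were called. The HOXA13 covariate gave 5 and 2 genes for uterus month 2 and month 6 with day 1, and the ciliated covariate 149 for the latter. With an estimated correlation 0 lists were called in each comparison, and with fry 0 in each within a tissue, 6 between tissues at day 1, 6 at month 6 and 1 for the difference.

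Leaving out 1 library at a time gave 0 to 2, 0 to 1, 0 to 1 and 6 to 322 genes for ovary month 2 with day 1, month 4 with month 2, month 6 with month 4 and month 6 with day 1, and 1 to 12, 0 to 0, 0 to 0 and 76 to 275 in the uterus. It gave 2472 to 3519 between tissues at day 1, 1552 to 2162 at month 6, 6 to 175 for the difference and 1 to 11 in both. Lists called ran from 11 to 16, 9 to 13, 9 to 17 and 8 to 15 in the ovary, 9 to 11, 9 to 11, 6 to 13 and 12 to 16 in the uterus, 10 to 12 and 8 to 11 between tissues and 6 to 11 for the difference. Without 1 library, 272 of 1340 results of called named genes lost the call and 4 of 300 others gained it.

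The individual number as a block pairs ovary with uterus, and the difference then gave 1 gene. Within a tissue it ties ages, across which it pairs no animals, so losses there say little. There ovary month 2 and month 6 with day 1 gave 0 and 6 genes, the latter all among the 15. Uterus month 6 with day 1 gave 127, 115 of them among the 266, and both tissues 0. Between tissues the block left HERC5 at day 1 uncalled (1.20, adjusted p = 0.0693) and called smooth muscle genes at day 1 (-0.295, 0.0403) and immediate early genes in the difference (0.23, 0.0433). It changed no other tissue call than these and those given above. Within tissues it left uncalled FHOD3 (0.0817), VLDLR (0.0958), 13 named uterus genes for month 6 with day 1 (0.0525 to 0.242), the ciliated list in ovary month 6 with day 1 (0.0719), steroidogenesis in ovary month 6 with month 4 (0.0513) and complement in uterus month 4 with month 2 (0.0725) and month 6 with month 4 (0.0654), and called granulosa genes in ovary month 4 with month 2 (0.0425) and mesothelial genes in uterus month 6 with month 4 (0.0393).

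Some lists changed the direction of their test. The value given is their median log2 change, which can keep its sign because the test sets a list against the other genes. With the HOXA13 covariate these were ciliated genes in uterus month 4 with month 2 (0.752) and month 6 with day 1 (0.568), and smooth muscle in the latter (-0.0317). With the ciliated covariate, which takes the change out of the ciliated list by construction, they were ciliated genes in ovary month 6 with month 4 (0.0554) and in uterus month 2 (0.056) and month 6 (0.0664) with day 1, and epithelial genes in ovary month 4 with month 2 (-0.00275) and month 6 with month 4 (0.251). Without the 3 uterus libraries rich in HOXA13 they were ciliated genes between tissues at day 1 (1.6) and in uterus month 6 with day 1 (1.44).

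Leaving out 1 library at a time turned the following, each with its range of medians. Ovary day 1 library 3 did so for month 6 with day 1 in matrix (-0.734 to -0.113) and smooth muscle genes (-0.552 to 0.428), and for month 2 with day 1 in oxidative phosphorylation genes (-0.348 to 0.208). Uterus month 4 library 5 did so for month 4 with month 2 in complement (-0.0835 to 0.784), endothelial (-0.319 to 0.455), matrix (-0.28 to 1.23) and epithelial genes (-0.466 to -0.0772). For month 6 with month 4 it turned complement (-0.719 to 0.0836), endothelial (-0.491 to 0.326) and matrix genes (-1.1 to 0.186). In each the end nearer to or past 0 came without that library, and again without both libraries together. Ovary month 4 library 5, the luteal one, turned for month 6 with month 4 antigen presentation (-0.302 to 0.15), cholesterol (-1.33 to 0.335), endothelial (-0.562 to 0.171), interferon (-1.28 to 0.143), oxidative phosphorylation (-0.35 to 0.0437) and steroidogenesis genes (-1.43 to 0.000275), and cell cycle genes (-0.289 to 0.34) at -0.052. It turned for month 4 with month 2 endothelial (0.0254 to 0.798) and interferon genes (-0.0447 to 1.55). Without all 3 libraries the same lists turned except endothelial genes in ovary month 4 with month 2, and myeloid genes in ovary month 6 with day 1 did too (0.438). Cell cycle genes were then at -0.0519, cholesterol at 0.336, oxidative phosphorylation at 0.0439, steroidogenesis at 0.000404, interferon in ovary month 4 with month 2 at -0.0446 and smooth muscle at 0.429. For month 6 with month 4, ciliated genes turned without ovary month 4 library 4 (-1.48 to 0.329) and without uterus month 6 library 3 (-1.38 to 1.6), and ovary cell cycle genes without month 6 library 3 (-0.289).

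Other splits of the same libraries into groups of 5, the real one included, were drawn: 60 of 126 within a tissue, 25 of 126 between tissues at an age and 25 of 31752 for the difference. For counts of called genes chance is argued against for uterus month 6 with day 1 (real count 266, highest other 184). The same holds for the tissues at day 1 (2913 and 591) and month 6 (2075 and 180), each with 1 split with as many. Not all possible splits were drawn, so chance is not excluded there. For uterus month 2 with day 1 (3 and 2, with 1 split) chance stays open, as the count of 3 became 1 without single libraries. It stays open for ovary month 2 (1 and 0; 1 split) and month 6 (15 and 236; 2 splits) with day 1: there as many genes had an unadjusted p under 0.05 in 14 (1488 genes) and 7 (2804) of 60 splits. It cannot be excluded for the difference (48 and 231; 2 splits). A real count of 0, which all 60 splits reach, says nothing for month 4 with month 2 (highest other 0 in either tissue) or month 6 with month 4 (86 in the ovary, 573 in the uterus). At an unadjusted p under 0.05 as many genes came up there in 3 and 56 splits in the ovary (1751 and 520 genes) and 18 and 19 in the uterus (1244 and 2028). The splits with 236, 86, 573 and 231 genes point to a structure of the samples, which was not tested further. Among splits that part 5 pairs, as the real one does, the highest other was 33 genes at day 1 (3 splits) and 6 at month 6 (5 splits). For lists chance could not be excluded in any comparison: the ovary steps, in the order of the DESeq2 counts, had 15 (highest other 17; 12 splits with as many), 10 (20; 56), 11 (19; 52) and 13 (19; 33), the uterus steps 9 (15; 30), 10 (18; 56), 8 (15; 58) and 13 (16; 4), the tissues at day 1 12 (17; 18) and month 6 8 (14; 21), and the difference 8 (19; 25).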

Other observations

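The tests of the ciliated genes and of the match within an age were chosen after the results were seen, and the comparison across ages was planned. Ciliated and oviduct epithelium genes parted the ovary libraries regardless of age: 8 libraries had a list score (mean log2 CPM) from 2.55 to 6.09 and 12 from -0.86 to 0.49, and every age held both kinds, with a range of at least 4.39 within an age. Age as the whole cause is argued against by that range and by the 90% of the variance that lay within ages (permutation p = 0.61). In the 8 libraries with the higher scores, log2 EPCAM, an epithelial adhesion gene outside the list, went with the score (r = 0.956, exact permutation p = 0.00055, adjusted p = 0.0022; rho = 0.929, p = 0.0022; r = 0.982 without the 2 farthest libraries), as did PAX8, a gene of oviduct epithelium (r = 0.813, p = 0.018, adjusted p = 0.036; rho = 0.69, p = 0.069; r = 0.818 without the 2 farthest). In the other 12 libraries r was 0.02 for EPCAM (permutation p = 0.89; rho = 0.371, p = 0.24; r = 0.729 without the 2 farthest) and -0.61 for PAX8 (p = 0.029, adjusted p = 0.039; rho = -0.671, p = 0.021; r = -0.429), 4 relations in all. Epithelium of the oviduct or its fimbria, carried along with some ovaries, is a candidate source, and epithelium of the ovary itself stays open.

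Some genes were either on or off in a goat, in both organs. Ovary and uterus libraries with the same number matched in 130 of 180 comparisons over 9 genes, above the highest of 100000 permutations within age (128; p = 1e-05, the smallest they can give), which is consistent with 1 goat behind each number within an age. LOC106502094, LOC108635065, LOC102184958 and LOC102179937 led (19 or 20 of 20 pairs, adjusted p from 0.0024 to 0.0073), while the other 5 matched in 9 to 12 pairs (adjusted p from 0.88 to 1). A feature tied to the number at every age is argued against by libraries of different ages, whose same numbers gave a mean of 100 matches.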
